A study of Mus musculus with 2 samples.

How the data were processed

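ATAC-seq libraries were made from flash-frozen neural retina of adult C57BL/6 mice, per the labels. There was 1 library from a wild-type mouse and 1 from a Gabra3 knockout littermate, each from 20000 nuclei with the Nextera DNA library preparation kit, sequenced on a NextSeq 500 with 75 bp single-end reads. Per the labels the authors used Trimmomatic 0.33, BWA and bedtools 2.23.0 with genome GRCm38 (mm10). The version of BWA, the role of each tool and any filter on duplicates are not given in the sources used here.

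The deposited files list 1 aligned read per line. The score column as deposited is the mapping quality of the read, left as the aligner gave it, with no normalization. The coordinate columns as deposited give the start and end of each read, and every read spanned 75 bp. The files held reads of chromosomes 1 to 19, X and Y and no line from mitochondrial DNA, so a mitochondrial share was not computed. Both libraries came from the same flow cell with 4 lanes each, as the read names show. The wild-type file held 9170838 reads and the knockout file 9038110, of which 93.6% and 93.4% had a mapping quality of at least 10.

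Counting started from the 5-prime end of each read with mapping quality at least 10, shifted by 4 bp on the plus strand and by -5 bp on the minus strand to the site of Tn5 insertion. Reads that repeated a position and strand were counted once, which left 7635799 wild-type and 7646373 knockout insertions. Open regions were called on the summed libraries at equal depth, and again in each library. Windows of 200 bp in steps of 50 bp with a Poisson p under 1e-05 against the larger of the genome mean and the mean of the surrounding 10000 bp were merged within 150 bp. The pooled call gave 36825 regions with a median width of 400 bp over 18.0 Mb.

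Gene positions came from a RefSeq gene table of GRCm38 that gives the start and end of a gene and no strand or exons. A promoter was therefore taken as the 500 bp either side of the gene end with more insertions summed over both libraries, for 21887 protein-coding genes. Of the 7509 promoters with at least 100 insertions, 7256 (96.6%) had over 4 times as many insertions at that end as at the other. Open regions over 1000 bp from both ends of every gene were treated as away from gene ends and named by the nearest protein-coding gene. Exon counts at Gabra3, motif groups and a correction for GC content were planned and not run, because they need exons or a genome sequence, which were not used here. The gene body of Gabra3 took the place of its promoter, which held too few insertions for a ratio.

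Ratios are log2 of knockout over wild type with a pseudocount of 0.5, scaled to autosomal insertions in the pooled open regions. The ratio of the Gabra3 gene body, which held no open region, was scaled to all autosomal insertions. With 1 library per genotype no test between groups and no p was computed. Each ratio has an exact (Clopper-Pearson) 95% interval from the split of the summed count, which covers counting error only. A promoter or region was counted as apart at 2-fold or more with at least 100 insertions summed. Beside each count stands what 100 binomial splits of the summed counts gave. For equal-depth region calls, 20 random divisions of the summed insertions into equal parts were called in the same way.

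The gene lists were rod, cone, bipolar, amacrine, horizontal, retinal ganglion, Muller glia, astrocyte and oligodendrocyte lineage, microglia and immune, vascular, retinal pigment epithelium and melanocyte, and lens markers. The others were GABA-A receptor subunits, GABA synthesis with transport, GABA-B receptors and inhibitory scaffold, glycine receptors and transporters, ionotropic glutamate receptors, photoreceptor ribbon synapse, immediate early genes, retinal stress and gliosis, circadian clock, and housekeeping genes. Gad1, Gad2, Slc32a1, Slc6a9, Grik1 and Gfap each stand in more than 1 list. A member counted as measured with at least 20 insertions summed. The median log2 ratio of a list was placed among 10000 random lists of the same size, matched on summed counts in 10 bins, and the summed counts gave 1 ratio with its interval. A region away from gene ends joined the list of its nearest gene within 50 kb.

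Named genes followed a rule: Gabra3, the 10 highest and 10 lowest promoters and regions with at least 100 insertions and the same direction on both strands, and in each list the 2 members with most insertions and the 2 with the largest ratio. Not all of these are named in the text. The lists, the rule for named genes, the 2-fold rule and most other settings tried were fixed before the data were examined. The strongest promoters and gene loci, the neighbours of Gabra3, the olfactory receptor genes and a few list members were named after their values were seen. Counts over all open regions of a gene and the 5 kb around it were added after seeing the gene table.

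Other settings changed the scaling (all autosomal insertions, trimmed mean of M values, loess on mean count), the treatment of repeated reads, the mapping quality minimum, the promoter window, the count minimum, the fold, the shift of read ends, the region threshold and the overlap rule. The code was tested on simulated data. Promoter counts were independent Poisson draws around the summed counts, and unchanged lists came from a binomial split of them. Regions were planted on a uniform background of the same mean density. Both settings are simpler than the libraries, so the recoveries check the code and need not hold for the libraries. Planted changes were recovered in 0 of 50 promoters at 1.5-fold, 24 of 50 at 2-fold and 50 of 50 at 3-fold and at 4-fold, and 0 of 7284 unchanged promoters were called. Planted regions of 300 bp were found in 183 of 200 cases at 10 times the background and in 200 of 200 at 20 and at 40 times. Of 500 unchanged lists 19 (3.8%) fell outside the central 95%.

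Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.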

Results

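Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, so that the number of insertions in a stretch of the genome reflects how accessible it was. The tissue was neural retina of adult C57BL/6 littermate mice, and the series asks how accessibility differs between wild-type mice and mice lacking Gabra3, the gene of the alpha 3 subunit of the GABA-A receptor. Each genotype had 1 library, made from 20000 nuclei and sequenced as 75 bp single-end reads. The wild-type library held 9170838 aligned reads and the knockout library 9038110. After removal of poorly placed reads and of repeats of a position and strand, 7635799 wild-type and 7646373 knockout insertions remained. With 1 library per genotype, every ratio below compares those libraries, not the conditions, and has no replicate check. Intervals are exact 95% intervals (Clopper-Pearson) and cover counting error only.

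The composition of the libraries was close. The X chromosome held 2.20% of wild-type insertions (2.19 to 2.21) and 2.17% of knockout insertions (2.16 to 2.18). The Y chromosome held 0.0699% (0.0680 to 0.0718) and 0.0697% (0.0679 to 0.0716), so the Y-linked levels lay within each other's intervals. Repeats of a position and strand made up 11.04% of well placed wild-type reads and 9.41% of knockout reads.

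Gabra3 itself held few insertions and no pooled open region. The gene spans 224 kb of chromosome X (72432676 to 72656919, GRCm38). Its body held 126 wild-type and 121 knockout insertions, a log2 ratio of knockout over wild type of -0.06 (-0.43 to 0.31), scaled to all autosomal insertions. The windows within 500 bp of its ends held 0 and 2 wild-type insertions and 2 and 0 knockout insertions, too few for a ratio. The window of 2 kb with most insertions within the gene lay at its end of higher coordinate in both libraries (72654676 to 72656675, with 8 wild-type and 6 knockout insertions). The gene table gave no strand, so whether transcription starts at this end was not established. The longest run of wild-type insertions with no knockout insertion between them counted 7, over 7.62 kb (72634717 to 72642334), and the longest run the other way also counted 7. Of 113 other X-linked genes over 100 kb, 89 had a run of at least as many wild-type insertions. At this depth a deletion of a few kb within Gabra3 was not detectable, so the locus does not check the genotype label. Among its neighbours, the GABA-A subunit genes Gabre and Gabrq had 9 and 7 insertions summed over both libraries at their promoters. The shared promoter region of Cetn2, a centrin gene, and Nsdhl, a gene of cholesterol synthesis, was open, with 62 and 51 insertions for Cetn2 (log2 ratio -0.22, -0.79 to 0.34).

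**Figure D1:**
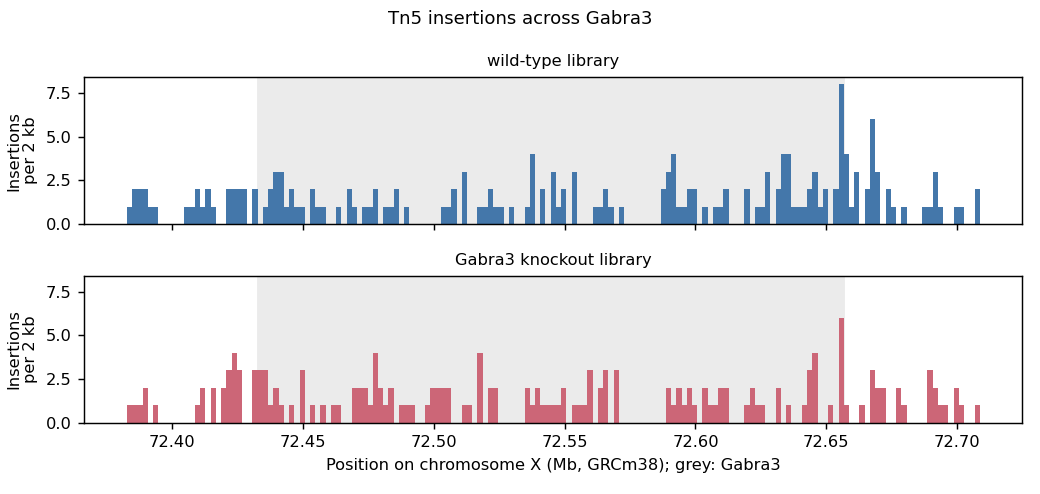
Insertions per 2 kb window (y axis, counts) along chromosome X (x axis, position in Mb) from 50 kb before to 50 kb after Gabra3, for the wild-type and the knockout library. Counts are low along the gene, whose body held 126 wild-type and 121 knockout insertions. Within it they are highest at its end of higher coordinate, with 8 and 6.

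In both libraries the strongest promoters included those of a kinase gene and a clock gene, and few olfactory receptor genes had an open region. The strongest promoters were those of Dnpep (aspartyl aminopeptidase; 486 wild-type and 458 knockout insertions), Gsk3b (a serine/threonine kinase; 446 and 417), Garem1 (439 and 416) and Dcaf6 (425 and 409). Nr1d2, a repressor of the circadian clock, ranked 7 with 365 and 352. Counted over all open regions of a gene and the 5 kb around it, Camta1 (1311 and 1344), a transcriptional activator gene, and Gse1 (1188 and 1137) ranked 2 and 3 of all genes, over 27 and 34 regions each. Of the olfactory receptor genes, which are silent in most tissues, 24 of 1110 (2.16%) had an open region, against 68.7% of all 21887 genes, and their promoters held a median of 1 wild-type and 2 knockout insertions.

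Signal over background was slightly lower in the knockout library. Of its autosomal insertions 18.8% (18.74 to 18.80) fell into the 36825 pooled open regions, against 19.6% (19.56 to 19.62) for wild type. Insertions within 50 bp of gene ends exceeded the level at 1900 to 2000 bp by 16.4 times in the knockout library and by 17.1 times in the wild-type library, each with a standard error of 0.684%. At equal depth 23815 regions were called in the knockout library and 26591 in the wild-type library, and 20 random divisions of the summed insertions into equal parts gave 25062 to 25368 regions per part. Of the knockout regions 83.5% overlapped a wild-type region, of the wild-type regions 74.7% overlapped a knockout region, and random parts overlapped by 78.2% to 79.0%. The 6716 regions called in the wild-type library alone were weak, with a median of 10 wild-type and 5 knockout insertions, and so were the 3933 called in the knockout library alone, with medians of 6 and 10. Because of this difference, scaling to all autosomal insertions in place of those in open regions lowered every log2 ratio by 0.06, and ratios are given relative to insertions in open regions unless stated otherwise.

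**Figure D2:**
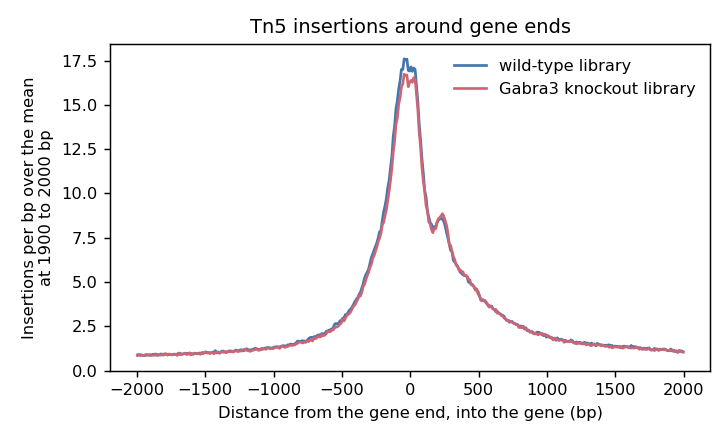
Insertions around the chosen end of 21887 protein-coding genes (x axis, distance in bp; y axis, insertions relative to the background at 1900 to 2000 bp) in the wild-type and the knockout library. Both curves peak 45 bp before the gene end, at 17.6 for wild type and 16.7 for the knockout; the means within 50 bp are 17.1 and 16.4.

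Promoter accessibility was nearly the same in both libraries where promoters held at least 100 insertions. Of 7509 promoters with at least 100 insertions summed over both libraries, 0 were 2-fold higher and 0 were 2-fold lower in the knockout library. For 7356 of them (98.0%) the interval of the ratio lay within 2-fold, and for 4611 (61.4%) within 1.5-fold. The log2 ratios had an SD of 0.19, below the 0.20 to 0.21 that splitting the summed counts at random gave, and with all repeated reads kept, where repeats count as separate molecules, 0.22 against 0.18 to 0.19. Neither comparison shows whether promoters varied beyond counting error. At 1.5-fold, 39 promoters were higher and 17 lower in the knockout library, and random splitting gave 18 to 47 higher and 21 to 48 lower. Scaling to all autosomal insertions turned this balance around, to 21 higher and 34 lower. Promoter counts of both libraries, on the log2 scale across genes, had a Pearson r of 0.95; genes are not independent replicates.

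The promoters that ranked lowest in the knockout library served varied functions. First came the window shared by Fam126b and Ndufb3, a subunit of mitochondrial complex I (chromosome 1, 58585833 to 58586833), with 94 wild-type and 49 knockout insertions and a log2 ratio of -0.87 (-1.41 to -0.37). Rdh8, the retinol dehydrogenase of photoreceptor outer segments, had 84 and 47 (-0.77, -1.33 to -0.25), and the window shared by the F-box genes Fbxo44 and Fbxo2 had 101 and 56 for Fbxo44 (-0.79, -1.29 to -0.31). Ccdc124, Abi1, Rnf6, Slc1a2 and Rras completed the 10 lowest, with log2 ratios from -0.76 to -0.72. For Slc1a2, a glutamate transporter, the ratio rested on the window: 66 and 38 insertions within 500 bp gave -0.73, and a window of 1000 bp either side gave -0.03.

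The promoters that ranked highest in the knockout library were led by the window shared by Vti1a, a SNARE protein of vesicle transport, and Zdhhc6, a palmitoyltransferase (chromosome 19, 55315530 to 55316530), with 47 wild-type and 84 knockout insertions for Vti1a and a log2 ratio of 0.89 (0.36 to 1.44). Rtn1, a reticulon of the neuronal endoplasmic reticulum, had 50 and 88 (0.87, 0.36 to 1.41). Chmp1b, a component of the ESCRT-III membrane scission machinery, had 60 and 97 (0.75, 0.27 to 1.24), and Aven had 68 and 107 (0.71, 0.26 to 1.17). Zfp184, Pomp, Uimc1 and Plekhh1 followed, with log2 ratios from 0.70 to 0.69. These promoters are extremes among 7509 and were picked by their size, and random splitting gave extremes of 0.97 on average, above the 0.89 seen.

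**Figure D3:**
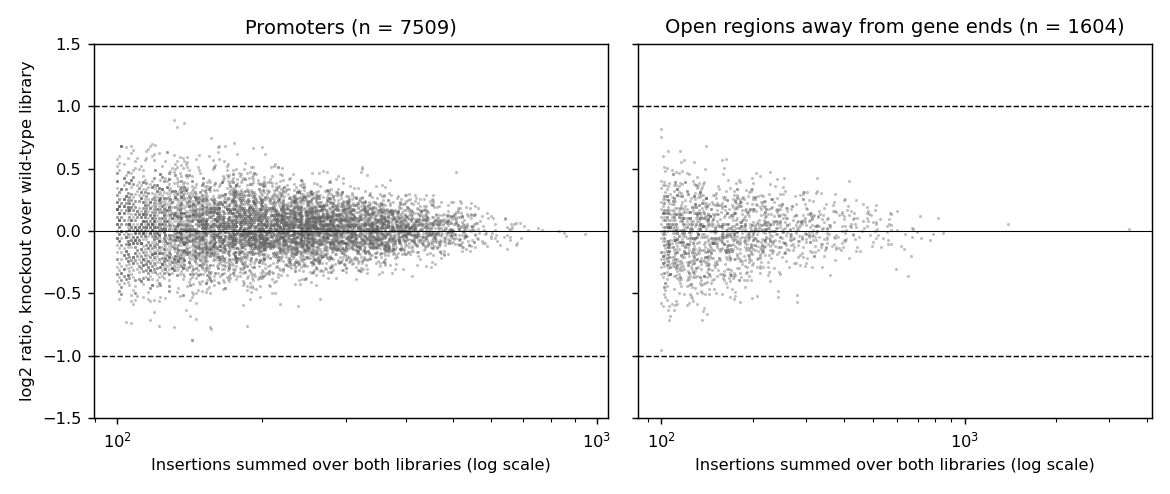
Log2 ratio of knockout over wild type (y axis) against summed insertions (x axis, log scale) for promoters and for open regions away from gene ends, 1 point per feature. No feature with at least 100 insertions reaches 2-fold, and the log2 ratios had an SD of 0.19 at promoters, where random splitting gave 0.20 to 0.21, and of 0.22 away from them, where it gave 0.22 to 0.24.

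Open regions away from gene ends gave the same picture where they held at least 100 insertions. With no minimum they did not: 880 were 2-fold higher and 1792 lower in the knockout library. Random splitting gave 1206 to 1353 higher and 1356 to 1570 lower. Of 23276 such regions 1604 had at least 100 insertions summed, and 0 of these were 2-fold higher and 0 were 2-fold lower in the knockout library. The interval lay within 2-fold for 1536 (95.8%), the SD of the log2 ratios was 0.22, and random splitting gave 0.22 to 0.24. With all reads kept the SD was 0.26, against 0.21 to 0.23. At 1.5-fold 6 were higher and 15 lower, where random splitting gave 5 to 19 and 4 to 21. Under other scalings the balance at 1.5-fold moved, to 3 higher and 29 lower with all autosomal insertions and to 11 higher and 7 lower with the trimmed mean of M values.

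The lowest of these regions in the knockout library lay inside Scn4a, a voltage-gated sodium channel gene (chromosome 11, 106344901 to 106345550), with 67 wild-type and 33 knockout insertions and a log2 ratio of -0.95 (-1.61 to -0.34). Regions inside Ldb1, the gene of a LIM-domain cofactor of transcription (86 and 50; -0.72, -1.26 to -0.20), and 7.11 kb from Mvk, the mevalonate kinase gene (67 and 39; -0.71, -1.33 to -0.13), came next. Regions in or nearest to Kdm6b, a histone H3K27 demethylase gene, Irs1, Ccn4, Peli2, Gm31665, Col2a1 and Fam78b followed, from -0.68 to -0.60. The highest lay inside Hook2 (37 and 63; 0.82, 0.22 to 1.45), 1.52 kb from Rbm12b2 (38 and 62; 0.76, 0.16 to 1.39) and inside Phactr1 (55 and 85; 0.68). Regions in Vldlr, Hdlbp, Plxnb1, Ccdc92b, Ncam1, Prrt4 and Maml3 followed, from 0.64 to 0.56. The nearest gene is given as a landmark, not as a target. These regions are extremes among 1604 and were picked by their size. Random splitting gave extremes of 0.93 on average and 1.37 at most, where 0.95 was seen.

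Rod photoreceptor genes, which mark the most numerous cells of the mouse retina, were slightly less accessible in the knockout library. Summed over all open regions of the 15 rod genes, 4363 wild-type and 3965 knockout insertions gave a log2 ratio of -0.08 (-0.14 to -0.02), and 11 of the 15 genes lay below 0. The list median of -0.07 stood at percentile 2.33 of 10000 random lists with matched counts; percentiles refer to list medians throughout, and ratios to summed counts. The ratio stayed below 0 under each scaling, at -0.14 (-0.20 to -0.08) with all autosomal insertions. That scaling lowers every log2 ratio by 0.06, so it could not have raised this one. Housekeeping genes over all open regions, scaled to open regions, had -0.07 (-0.16 to 0.02), close to the rod ratio of -0.08. At promoters the rod markers had -0.10 (-0.22 to 0.02; percentile 3.91), with Reep6 at 209 and 202 insertions, Gnat1, the rod transducin gene, at 157 and 137, and Slc24a1, the rod sodium/calcium exchanger gene, at 61 and 35 (174 and 129 over its open regions). Open regions away from gene ends nearest to rod genes had -0.10 (-0.21 to 0.00; percentile 1.42). Cone photoreceptor markers had 217 and 234 insertions at promoters (0.17, -0.10 to 0.44; percentile 59.6) and 0.00 (-0.13 to 0.13) over all open regions. Among them Gnb3 had 75 and 69 at its promoter, and Thrb, the thyroid hormone receptor of cone opsin patterning, had 28 and 47, but 337 and 340 over all its open regions.

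Among inner retinal neurons, promoters of retinal ganglion cell markers were higher in the knockout library and those of bipolar cell markers leaned the same way. The 7 measured ganglion cell promoters held 152 wild-type and 218 knockout insertions, a log2 ratio of 0.58 (0.27 to 0.89), and 6 of the 7 were above 0 (median 0.57, percentile 99.5). Tubb3, a neuronal tubulin gene, had 67 and 92 insertions, Nefh, the heavy neurofilament gene, 36 and 52, and Pou4f1, a ganglion cell transcription factor gene, 10 and 23 (4 and 14 in its open region). Over all open regions of the 6 list genes measured that way the ratio was 0.26 (0.04 to 0.49), and 0.20 (-0.03 to 0.43) with all autosomal insertions, while open regions away from gene ends, measured nearest to 4 genes of the list, had -0.11 (-0.35 to 0.13). The 12 bipolar cell promoters had 273 and 321 insertions (0.29, 0.06 to 0.53; percentile 97.5), with Prkca at 97 and 111, Nyx at 12 and 20 (76 and 90 over its open regions), and 9 of 12 above 0. The bipolar interval reached 0 with all autosomal insertions (0.23, -0.01 to 0.47), and over all open regions the ratio was 0.07 (-0.08 to 0.22). Amacrine cell promoters had -0.17 (-0.56 to 0.21; percentile 35.1), with Meis2 at 54 and 50, and horizontal cell promoters had -0.52 (-1.33 to 0.26; percentile 6.21) from 36 and 24 insertions at Onecut1 and Onecut2.

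The promoter intervals of glial and non-neuronal markers all included 0. Muller glia markers had 308 and 267 insertions at 10 promoters (-0.15, -0.39 to 0.09; percentile 7.72), with 9 of 10 below 0 and Glul, the glutamine synthetase gene, at 111 and 100. Of the astrocyte and oligodendrocyte lineage markers the promoter of Mbp alone was measured, at 92 and 97 (0.14, -0.29 to 0.56; percentile 73.2). Microglia and immune markers had 0.00 (-0.43 to 0.43) and a list median of -0.19, with Spi1, a myeloid transcription factor gene, at 20 and 16. Of the vascular markers the promoter of Des alone was measured, at 10 and 12 (0.31, -1.01 to 1.69; percentile 66.6). Lens markers had 0.08 (-0.20 to 0.35; percentile 85.7). Retinal pigment epithelium and melanocyte markers had 288 and 283 at promoters (0.03, -0.21 to 0.28; percentile 66.3), but their 6 open regions away from gene ends held 173 and 125 (-0.41, -0.75 to -0.07), with the median at percentile 1.39.

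Genes of inhibitory transmission, the lists closest to the knocked-out gene, had no list ratio that stood apart from counting error under every way of counting. The 7 measured GABA-A receptor subunit promoters held 206 wild-type and 157 knockout insertions, a log2 ratio of -0.33 (-0.64 to -0.03; percentile 4.84 for the median), with 4 of 7 below 0. Among them Gabra5 had 66 and 42 (113 and 86 over its open regions), and Gabra2 had 37 and 29. Some windows of the list overlap: with each insertion counted once, a choice made after seeing the data, the GABA-A promoters held 168 and 135, and the interval reached 0 (-0.26, -0.59 to 0.08). With all reads kept it reached 0 as well (-0.22, -0.50 to 0.06), and over all open regions, counted once, the ratio was -0.12 (-0.35 to 0.11). Genes of GABA synthesis, transport, GABA-B receptors and the inhibitory scaffold had 545 and 525 (0.01, -0.17 to 0.18; percentile 64.7), with Slc12a2, a chloride importer gene, at 183 and 183. Glycine receptors and transporters had 100 and 88 (-0.12, -0.56 to 0.30; percentile 35.6), and ionotropic glutamate receptors had 154 and 144 (-0.04, -0.38 to 0.30; percentile 43.6), with Grin1, the obligate NMDA receptor subunit, at 22 and 9 (13 and 8 in its open region). The photoreceptor ribbon synapse had 962 and 887 (-0.06, -0.19 to 0.08; percentile 10.7), with Cacna1f, the photoreceptor calcium channel gene, at 33 and 13 (105 and 95 over its open regions) and Pclo at 115 and 125.

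Genes that respond to light, activity or injury showed no common direction at promoters. Immediate early genes had 1125 wild-type and 1102 knockout insertions (0.03, -0.09 to 0.15; percentile 38.8), with Jun at 185 and 175, Egr1 at 170 and 139 and Arc at 32 and 53 (29 and 49 in its open region). The circadian clock list had 1893 and 1831 (0.01, -0.08 to 0.10; percentile 37.1), with Per2 at 290 and 256. Retinal stress and gliosis genes had 312 and 292 (-0.04, -0.27 to 0.20; percentile 43.4), with Stat3 at 210 and 192 and Edn2, an endothelin gene induced by photoreceptor damage, at 13 and 21 (17 and 20 over its open regions). Housekeeping genes had 1252 and 1129 (-0.09, -0.21 to 0.03; percentile 15.8), with Eif4a1 at 212 and 161. Of the 21 lists, 1 median lay outside the central 95% of random lists at promoters, with the bipolar one on the limit and not counted, 2 away from gene ends and 1 over all open regions of the genes, where chance gives 1.05 each. The interval of the summed ratio, scaled to open regions, excluded 0 for 3 lists at promoters, 1 away from gene ends and 2 over all open regions. How many chance gives was not worked out for these intervals. Of the 3 promoter lists, GABA-A receptor subunits reached 0 with each insertion counted once, and bipolar cell markers with all autosomal insertions.

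**Figure D4:**
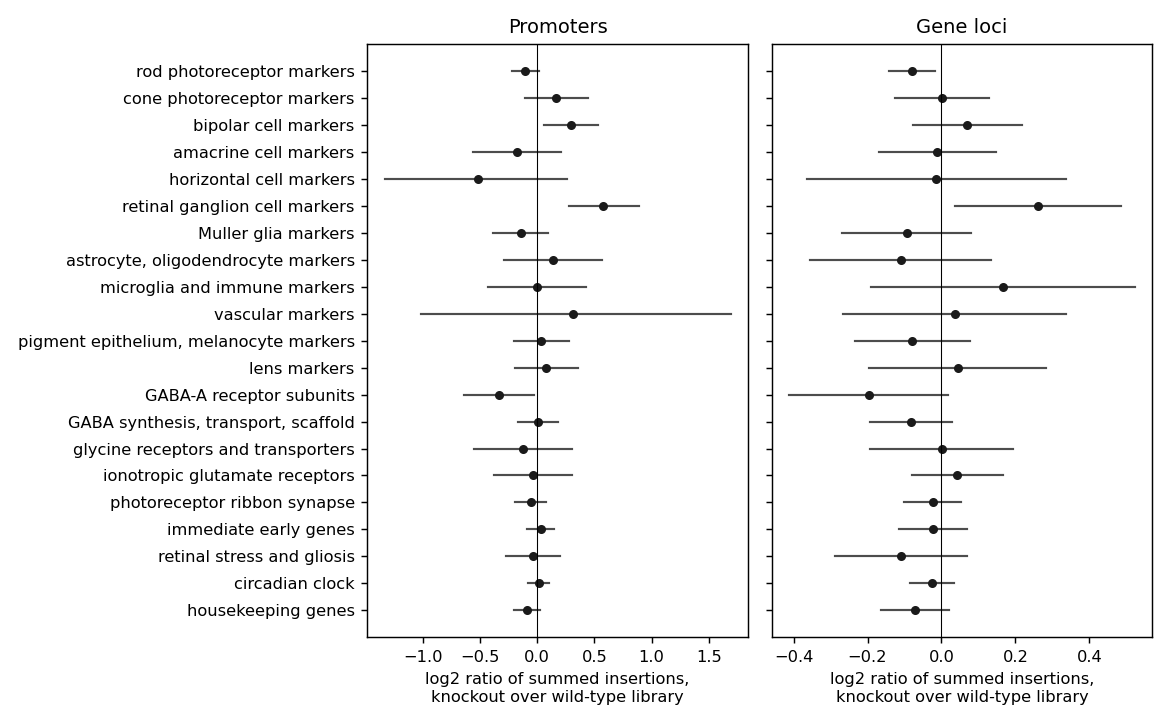
Log2 ratio of knockout over wild type of the insertions summed over each of the 21 gene lists (x axis, with a different scale in each panel; y axis, lists), at promoters and at gene loci, which are all open regions of a gene and the 5 kb around it. Points are the ratio and bars its exact 95% interval for counting error; ganglion cell markers lie above 0 in both panels (0.58 and 0.26), and rod markers lie below 0 at gene loci (-0.08).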

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

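Tests of unequal depth, of the scaling and of a larger share of ganglion cell nuclei, and the test of broad differences against counting error, were chosen after the result they measure had been seen, and the tests of unequal depth (in its measure) and of ganglion cell nuclei (in its genes and in how it is read) were then revised with their values known.

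Reads with mapping quality under 10, used only where no mapping quality minimum was set, made up 6.61% (6.60 to 6.63) of the knockout library and 6.40% (6.39 to 6.42) of the wild-type library. Reads piled up at few positions in 15 windows of 5 kb, and 4 of these held more reads per library size in the knockout library: chromosome 2 from 98660001 (2466 wild-type and 2780 knockout reads) and from 98665001 (14940 and 16362), chromosome 6 from 103645001 within Chl1 (3356 and 3681), and chromosome X from 143480001 (656 and 727). The log2 ratios of these 4 were 0.16 to 0.20. The other 11 windows held fewer reads in the knockout library, 163870 and 129004 in all, with log2 ratios from -0.44 to -0.22. The densest of them, on chromosome 1 from 24610001, held 84884 wild-type and 67620 knockout reads at the pseudogenes Gm10222 and Gm10925.

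The first pattern weighed is the lower signal over background of the knockout library. The test of unequal depth does not decide, since the deeper library depends on the measure. After collapsing of repeats the knockout library held slightly more insertions (7646373 against 7635799, log2 ratio 0.0020, 0.0005 to 0.0034). Before collapsing it held fewer well placed reads (8440250 against 8583654). With insertions after collapsing thinned to equal depth, fewer regions were still called in the knockout library (23815 against 26591, where random parts gave 25062 to 25368). For the number of regions, this argues against unequal numbers of insertions, but it does not cover the reads before collapsing. Neither the collapsing of repeated reads nor pile-ups account for the lower signal. With all reads kept and the pile-up windows left out, the log2 ratio of the shares in open regions stayed at -0.0767 (-0.0793 to -0.0742). Keeping all reads cannot test the repeated reads themselves. With repeats collapsed and those windows left out, the shares were still 18.7% for the knockout and 19.5% for the wild-type library. A single deviating sequencing lane is argued against as well. With repeats collapsed within each lane, the highest knockout lane reached 21.7% and the lowest wild-type lane 22.6%. These shares are not comparable with those of whole libraries, where repeats were collapsed across lanes. Both libraries ran on the same 4 lanes, so such a lane would have touched both. Genotype, animal and library preparation coincide with 1 library each, so all of them stay open and untested.

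The second pattern is the higher ratio at promoters of retinal ganglion cell markers in the knockout library. The choice among scaling to open regions, to all autosomal insertions and by the trimmed mean of M values is argued against at promoters. The lowest lower bound over these was 0.21. Each of them shifts all promoter ratios by 1 constant. All autosomal insertions lower them by 0.06, so this outcome followed from the lower bound of 0.27. Loess gave no summed ratio and was not part of this test. Over all open regions of the list genes, scaling to all autosomal insertions did bring the interval to equality. A larger share of ganglion cell nuclei stays open: over all measured genes the regions away from gene ends had an upper bound of 0.13, below the lower bound of 0.27 at promoters, but these were partly different genes, and for the 3 genes measured at both (Nefh, Opn4 and Rbpms) the upper bound of 0.11 (306 wild-type and 268 knockout insertions) reached the lower bound of 0.09 at promoters (54 and 79), which the first reading would have counted in its favour. Counting error was weighed on list medians alone: in 23% of 200 binomial splits at least 1 of the 21 promoter lists lay as far out in percentile. Each split was ranked against its own random lists, so this share mostly reflects the number of lists. It does not judge the summed ratio, for which counting error over many lists was not tested. A change of these promoters with genotype stays open and was not tested, for want of replicates.

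The third pattern is a set of broad differences outside open regions, such as more knockout insertions over 500 kb at Cdh23, Slc29a3 and Unc5b (2741 wild-type and 3323 knockout; log2 ratio 0.26, 0.19 to 0.33) and fewer at Tenm4 (1253 and 1015; -0.32, -0.44 to -0.20). Counting error alone is argued against, since the dispersion over bins of 500 kb was 1.84 and binomial splits gave 0.96 to 1.07. A trend with background density accounts for part at most, since a dispersion of 1.57 remained after its removal. A regional change in all reads alike, such as copy number, stays open: open regions followed the background with a slope of 0.82 (0.68 to 0.98). An upper bound this near 1 cannot argue against it, because repeats were counted once. Counted so, promoter ratios had an SD of 0.19, below the 0.20 to 0.21 of random splitting. Ratios of dense regions, and with them the slope, may therefore be narrowed. GC content was not analysed here and stays open, as does a difference by genotype or animal.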

How the results depend on the processing

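Results over both ends of every gene, without the pile-up windows, with 1 window for overlapping promoters, with insertions counted once per list and at 1.5-fold under other scalings or with all reads kept, and the random splits at lower minimums, were chosen after the data had been seen. In all settings run the knockout library stayed below the wild-type library in the share of insertions in open regions and in gene end enrichment, and no ratio with an interval that excluded 0 changed its sign. Counts of promoters and regions 2-fold apart depended on the minimum. With at least 50 insertions 2 promoters were higher and 2 lower, where 100 random splits gave 0 to 11 and 1 to 11, and 3 and 8 regions away from gene ends, where they gave 3 to 15 and 4 to 15. With no minimum the counts left the range of the splits: 1831 promoters were higher and 1664 lower, against 1580 to 1782 and 1764 to 1943, and 880 and 1792 regions, against 1206 to 1353 and 1356 to 1570. At 1.5-fold 39 promoters were higher and 17 lower, and 6 and 15 regions. With all reads kept 2 promoters were higher, and 2 regions were higher and 2 lower. Scaling to all autosomal insertions put 1 region at 2-fold lower, and so did unshifted read ends, with 1 region. The same 1.5-fold counts with all reads kept were 79 and 38 promoters and 32 and 42 regions, and with loess scaling 10 and 9 regions. In values for wild type and then knockout, the share in open regions was 25.9% and 24.4% with all reads, 17.5% and 16.8% at a Poisson p under 1e-08, 19.5% and 18.7% without pile-up windows, and 24.0% and 22.8% with all reads and without those windows. Gene end enrichment was 23.7 and 22.3 with all reads, 16.5 and 15.8 with no mapping quality minimum, and 8.86 and 8.49 over both ends of every gene. The percentage of regions shared was 74.0 and 82.2 with all reads, 72.4 and 80.9 at 50% reciprocal overlap, and 81.1 and 88.3 at a Poisson p under 1e-08. The X chromosome held 2.10% and 2.08% with all reads and 2.58% and 2.56% with no mapping quality minimum. The Y chromosome held 0.0650% and 0.0654% with all reads and 0.954% and 0.952% with no mapping quality minimum. The cause of these differences was not tested. Of the ratios of single genes and regions, 837 of 851 values under other settings stayed within the interval of the main setting. Of the values of gene lists, 773 of 775 stayed. A list median has no interval, and counted as staying if it moved no further than the interval of the summed ratio reaches to either side. All settings reuse the same reads, so staying within these intervals was likely beforehand and says little about robustness. The circadian clock loci moved to -0.09 (-0.15 to -0.03) with all autosomal insertions. Leaving out a library could not be run with 1 library per group, and no paired analysis was possible because each group holds 1 library. A correction for GC content, exon counts and motif groups were not run. Depth limits the comparison: the median promoter interval reached 0.41 log2 either side. In simulated data the 2-fold rule recovered 0 of 50 changes of 1.5-fold and 24 of 50 of 2-fold. These recoveries do not measure the limit set by depth, because the planted changes lay below the 2-fold cut or right at it.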

Other observations

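The values given here were chosen after they had been seen, and no test was run on them.

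Other stretches of 500 kb differed between the libraries outside open regions. Over 500 kb of chromosome 2 that hold Chst1, Syt13 and Prdm11, 1434 wild-type and 1812 knockout insertions lay outside open regions (log2 ratio 0.32, 0.22 to 0.42), and their open regions held 112 and 114. At Tenm2 the background held 981 and 807 (-0.30, -0.43 to -0.16) and the open regions 67 and 50, and at Fstl5 the background held 773 and 636 (-0.30, -0.45 to -0.15) and the open regions 92 and 65. The dispersion over bins, which is measured against counting error, grew with their size, from 1.14 at 50 kb to 2.37 at 1000 kb. Larger bins also held more insertions, with a median of 203 at 50 kb and 4153 at 1000 kb, so counting error was smaller there. The SD of the log2 ratios fell from 0.22 to 0.06, so the growth does not mean larger differences over longer stretches.

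The most insertions of any gene lay at Myo3a, a myosin gene of hair cells and photoreceptors, with 1772 wild-type and 1717 knockout insertions in 1 open region. That region lies in a window of piled-up reads on chromosome 2 from 22585001, with 24733 wild-type and 19281 knockout reads. The libraries were not copies of each other: pairs of lanes shared 270081 positions within the wild-type library and 228846 within the knockout library, against 187731 to 190611 across libraries.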
